A study of Mus musculus with 10 samples.

How the data were processed

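RNA sequencing of 10 libraries was analysed, 2 each from wild type E14 mouse embryonic stem cells and from lines without isoforms a and b, without c, without all 3, and without a and b with c carrying a deletion (Mbd3cΔN-ab KO). Per the labels' protocols, total RNA was depleted of ribosomal RNA with reagents of 2 suppliers and made into strand-specific libraries. Which supplier served which library is not given in the sources used here. Per the submitters' processing notes the tools were TopHat2, HOMER and DESeq2 and the build was mm10. Per the file headers HOMER counted exon reads on the minus strand setting, with transcripts condensed to genes. Aligner settings and tool versions are not given in the sources used here.

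The authors deposited 4 tables, 1 per mutant, each with the wild type and mutant libraries of that comparison, and each lists only genes called in it. The read columns hold a normalized signal that the authors deposited per library, scaled to equal totals within each table. The authors' deposited columns also give a log2 fold change with its SE and a p-value with its adjusted value, from DESeq2 per the file headers. A score column as deposited, the Wald statistic that DESeq2 made from log2 fold change and SE per the file headers, was not used. The tables held 443, 38, 8141 and 6000 genes, of which 1, 0, 9 and 11 had an adjusted p of 0.05 or more and were left out. Columns were assigned to groups, not to replicate numbers, and whether the 2 libraries of a mutant came from separate clones is not given in the sources used here.

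Every value in the read columns was a whole multiple of a step particular to its library, within 0.006 (100% of values in each library), so reads were recovered by division. In the short Mbd3ab KO and Mbd3c KO tables too few low values were present to establish this from the table alone. There it rests on the values being whole and on the wild type reads, which equalled those of the other tables for all genes listed with the same transcript. Size factors came from the linear relation of the deposited mean level to the columns, and levels are printed as reads divided by these size factors, mean ± SD of 2 libraries. Levels of wild type differ between tables because each was normalized separately: the size factor of the first wild type library was 1.10 in the Mbd3c KO table and 0.777 in the Mbd3abc KO table. Levels are therefore comparable within a table only. Folds are ratios of group means, given only where each group had more than 3 reads. They are not shrunken, unlike the deposited log2 fold changes. The number of genes tested, recovered from the relation of p to adjusted p, was 13201, 10759, 15622 and 14429.

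The main results are the authors' calls at an adjusted p of 0.05, since the tables hold selected genes. As alternatives chosen after seeing the data, the listed genes were tested again with 3 tools, adjusted with the recovered number of genes tested. They were tried in this order: limma 3.58.1 on log2(normalized reads + 1), then edgeR 4.0.16 (quasi-likelihood) on recovered reads, after limma had called no gene in Mbd3ab KO and Mbd3c KO, then DESeq2 1.42.0 with a fold change prior, after edgeR had done the same. DESeq2 is the tool behind the deposited calls, so its refit is no independent test. It also replaced edgeR for leaving out each library, after the edgeR values had been seen, where the lone library of a group is assumed to vary like the other group. These refits take the spread from called genes only. Tested on simulated data from the Mbd3ab KO genes (443 genes), 2-fold changes were recovered at 41.1% by limma, 56.2% by edgeR and 64.4% by DESeq2. In the Mbd3abc KO genes (8141 genes) the same shares were 0%, 59.4% and 68.1%, and false calls made up 46.4%, 3.6% and 20.1% of calls. The simulated p-values were adjusted over the simulated genes alone, not over the recovered number of genes tested (13201 and 15622) as in the refits. These shares therefore do not give the recovery that the refits had. The edgeR contrast of Mbd3abc KO and Mbd3cΔN-ab KO recovered 70.5% of simulated 2-fold changes, with 10.8% false calls, on 5404 genes. R 4.3.3, Python with scipy and GENCODE M21 transcripts (for GC content, matched for at least 92.1% of genes in each table) were used.

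Direction was described with exact two-sided binomial tests, and 24 gene lists fixed before the data were examined with two-sided Fisher's exact tests of higher against lower, members against the other called genes, Benjamini-Hochberg adjusted over 65 tests. The lists of Hox genes and mitochondrial transcripts had no called member. In the GC comparison, chosen after seeing the data, the number of called members that were higher was set against 10000 simulated draws. In each draw a member was higher with the share of called genes higher in its GC bin, of 20 bins of the same table. The members themselves were part of these shares. On simulated random lists it passed 3% and 2% at p under 0.05 and recovered 100% of planted lists in both mutants. Counts adjusted over the list alone use the deposited p of the listed members and all members as tested, and are lower limits, since members outside the tables have no p. Where a larger share of a list than of all genes tested was called, every called member passes by construction. Such a count is no separate check. Numbers to expect for independent lists take all calls of both mutants to lie within the smaller of their 2 numbers of genes tested. Shared controls were simulated 20 times per pair, with levels and spread taken from the Mbd3abc KO table. The simulated r, covariance and share of equal sign do not require a call in the simulation. Observed genes were called in both mutants, so the simulated values do not reproduce that selection. Named genes were fixed by a rule before the data were examined: NuRD subunits, up to 4 called members per list with the largest absolute log2 fold change, the 8 that rose and 8 that fell most above the median mean level, all genes called in all 4 mutants and those in at least 3. Wdr5, Socs2 and the genes of opposite sign were named outside the rule, after their values were seen. Alternatives were an adjusted p of 0.01, a minimum of 2-fold, only genes above the median mean level, each library left out, and, chosen after seeing the data, no chromosome 8 and only the middle of 5 GC classes. The p-values of DESeq2, edgeR and limma rest on the spread between 2 libraries per group, estimated with help from other genes. The binomial, Fisher and GC-matched p-values are across genes and measure no spread between libraries. A comparison of 2 against 2 alone cannot go below an exact p of 0.333.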

Results

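Total RNA depleted of ribosomal RNA was sequenced from mouse E14 embryonic stem cells and from 4 mutant lines made from it with CRISPR/Cas9. Mbd3 is the methyl-CpG binding domain subunit of the NuRD complex, which joins nucleosome remodelling to histone deacetylation, and the labels distinguish its isoforms a, b and c. Mutations lay in exon 2 of Mbd3 in the Mbd3ab KO and Mbd3cΔN-ab KO lines, in intron 2 in the Mbd3c KO line and in exon 5 in the Mbd3abc KO line. Each of the 5 groups held 2 libraries, described in the labels as biological replicates. Every mutant was compared with the same 2 wild type libraries, to ask which genes depend on which isoform and, by the series title, on a NuRD form that interacts with Wdr5. The deposited tables list only genes the authors called, so a gene missing from a table has no value here. Relative to the first wild type library, the second had 1.59 times the total reads. The mutant libraries had 1.23 and 0.71 times in Mbd3ab KO, 1.02 and 0.485 times in Mbd3c KO, 1.23 and 1.33 times in Mbd3abc KO, and 0.94 and 1.38 times in Mbd3cΔN-ab KO. Absolute totals are unknown, because the tables hold part of each library.

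Mbd3 RNA, read from chromosome 10, 80392541 to 80399479 of mm10, fell in 3 of the 4 mutants, in both libraries of each. In the Mbd3ab KO table it went from 1495 ± 39.0 normalized reads in wild type to 572 ± 93.4 in the mutant (SD, n = 2 each), 2.61-fold lower. It was 13.0-fold lower in Mbd3abc KO, at 133 ± 35.4 normalized reads, and 5.57-fold lower in Mbd3cΔN-ab KO, at 296 ± 5.23 (SD, n = 2). In the authors' deposited table, the DESeq2 log2 fold changes were -1.31 ± 0.20 (SE), -3.59 ± 0.23 and -2.44 ± 0.13, with adjusted p = 5.96e-08, 2.56e-51 and 1.02e-74. Mbd3 was not among the called genes of Mbd3c KO, and reads summed over the gene do not separate the isoforms. Among the other NuRD subunits, the neural remodeller Chd5 rose 2.11-fold in Mbd3ab KO, from 178 ± 1.34 to 374 ± 0.986 normalized reads. In Mbd3abc KO the related methyl-CpG binding gene Mbd2 rose 4.26-fold and the deacetylase Hdac2 2.34-fold, while the remodeller Chd4 fell 1.74-fold. The same 3 genes moved the same way in Mbd3cΔN-ab KO, where Mbd2 rose 2.41-fold, Hdac2 rose 2.04-fold and Chd4 fell 1.53-fold.

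In Mbd3ab KO 442 genes were called at the authors' adjusted p of 0.05, 271 higher and 171 lower. The basement membrane collagen genes Col4a1 and Col4a2, neighbours on chromosome 8, rose most among genes above the median mean level. Col4a1 went from 87.7 ± 8.74 to 1055 ± 470 normalized reads (SD, n = 2), 12.0-fold, and Col4a2 from 53.8 ± 12.1 to 437 ± 106, 8.11-fold. The early germ cell and pluripotency gene Dppa3 fell 13.0-fold, to 14.1 ± 13.5 normalized reads, and the Wnt effector Lef1 fell 7.55-fold, from 266 ± 15.6 to 35.3 ± 26.8. In the authors' deposited table the DESeq2 log2 fold change was 3.01 ± 0.31 (SE) for Col4a1, with adjusted p = 5.91e-18, and -2.43 ± 0.39 for Dppa3, with adjusted p = 2.36e-07.

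Several groups fixed before the data were examined held called members in Mbd3ab KO. All 5 called epithelial and adhesion genes were higher, among them the laminin gene Lamb3, which rose 7.55-fold, the claudin Cldn7, which rose 2.86-fold, the integrin Itgb4, which rose 2.78-fold, and the keratin Krt8, which rose 2.94-fold. Of 4 called germline genes 3 were higher: Sohlh2, a germ cell transcription factor, rose 4.46-fold, Dazl, an RNA-binding protein of germ cells, rose 4.65-fold, and Mov10l1, of the piRNA pathway, rose 2.71-fold, while Tex19.1 fell 1.96-fold. All 4 called p53 targets were higher, including Pmaip1 at 2.77-fold and Btg2 at 2.11-fold. All 4 called genes of the glycolysis list were lower: the enzyme Tpi1 fell 2.04-fold, the lactate transporter Slc16a3 1.83-fold, and Egln3 and Bnip3, which respond to hypoxia, 2.65-fold and 1.81-fold. Of 9 called trophectoderm and placenta genes 5 were higher and 4 lower, with Eomes rising 2.54-fold. Otx2, a gene of the formative state, rose 2.54-fold, while Lefty1, a Nodal antagonist, fell 2.41-fold and the naive state gene Nr0b1 fell 1.81-fold. The imprinted gene Peg3 fell 2.69-fold. No list differed in direction from the other called genes of this table after adjustment over 65 tests. The smallest Fisher exact p, two-sided, was 0.0219 for glycolysis, with adjusted p = 0.123. Every called member was also past the threshold when adjusted over the list alone, with 5 epithelial, 4 germline, 4 p53 and 4 glycolysis genes. For these 4 lists the calls fixed this in advance. Of all genes tested 3.35% were called, and a larger share of each list was, so the counts are no separate support.

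Among genes above the median mean level, the 8 that fell most in Mbd3ab KO included the axon guidance gene Ntn1, which fell 3.35-fold from 1458 ± 146 to 436 ± 116 normalized reads, the neuronal intermediate filament gene Ina, which fell 3.32-fold, the transcriptional repressor Bhlhe40, which fell 3.07-fold, and the kinase Jak3, which fell 3.20-fold. Among those that rose, the transcription factor Nfatc2 was 4.67-fold higher and the actin-binding gene Ablim1 4.44-fold higher. The 442 calls rest on the authors' DESeq2 test. Refits of the listed genes on recovered reads, all chosen after seeing the data, called 0 genes with limma, then 0 with edgeR's quasi-likelihood test, then 434 with DESeq2, although all 442 had an unadjusted p under 0.05 in each of the 3. In a DESeq2 refit without a wild type library 72 or 77 genes stayed past the threshold, against 242 or 303 without a mutant library. Without a wild type library 376 and 381 genes kept an unadjusted p under 0.05, and no sign changed. Among genes above the median mean level 46.4% were higher, against 61.3% of all 442 (exact binomial p = 0.314 and 2.27e-06).

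The Mbd3c KO table was short, with 38 genes, 34 higher and 4 lower. Histone and other short RNAs that lack or largely lack a poly(A) tail made up 61.8% of the genes that rose, 10 histone genes and 11 small non-coding RNAs. Hist1h2ac rose 7.59-fold, from 71.3 ± 24.0 to 541 ± 89.2 normalized reads (SD, n = 2), and Hist1h4d rose 4.38-fold. Rmrp and Rpph1, the RNA parts of RNase MRP and RNase P, rose 4.17-fold and 4.52-fold. The 4 genes that fell were the growth factor gene Bmp4, at 3.84-fold, Enox1, at 3.85-fold, the imprinted gene Peg3, at 3.46-fold, and the cytokine signalling inhibitor Socs2. In the authors' deposited table the DESeq2 log2 fold change was 2.24 ± 0.38 (SE) for Hist1h2ac, with adjusted p = 2.19e-05, and -1.55 ± 0.36 for Bmp4, with adjusted p = 0.00642. All 6 called members of the histone list were higher, but 34 of the 38 called genes were, and Fisher's exact test gave adjusted p = 1. All 6 also passed when adjusted over the list alone, which the calls fixed in advance. Leaving out either wild type library left 0 or 1 of the 38 calls in a DESeq2 refit of the listed genes, and leaving out either mutant library left all 38. Refits with all libraries called 0 with limma, 0 with edgeR and 37 with DESeq2, with all 38 at an unadjusted p under 0.05 in each.

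In Mbd3abc KO 8132 genes were called, 52.1% of those recovered as tested, with 4240 higher and 3892 lower (exact binomial p = 0.000119). Germline genes rose: 19 of 23 called members were higher and 4 lower. Dazl rose 42.7-fold, from 15.5 ± 0.0315 to 661 ± 208 normalized reads (SD, n = 2), Tex15 rose 37.5-fold and the meiotic cohesin Smc1b 12.0-fold. Glycolysis genes fell, 19 of 19 called members, with Tpi1 8.50-fold lower, Slc16a3 7.26-fold lower and the glucose transporter Slc2a1 4.85-fold lower. Replication-dependent histones also fell, 16 of 16, Hist1h1c by 4.96-fold. All 8 called neuroectoderm genes fell, among them Gbx2 at 9.25-fold and Sox21 at 6.01-fold. By Fisher's exact test against the other called genes the adjusted p was 5.28e-05 for glycolysis, 0.000242 for histones, 0.0334 for germline genes and 0.0334 for neuroectoderm genes. Adjusted over the list alone, the counts past the threshold were 19, 16, 23 and 7. For all but the neuroectoderm list the calls fixed this in advance. The germline list lost its call under each alternative, with adjusted p = 0.0528 at an adjusted p of 0.01, 0.0637 with at least 2-fold change, 1 above the median mean level (2 higher, 2 lower) and 0.0525 without chromosome 8. The neuroectoderm list lost its call at 0.01 (0.0528), above the median mean level (1) and without chromosome 8 (0.0561). Other short non-coding RNAs fell with the histones, 41 of 60 in Mbd3abc KO and 31 of 41 in Mbd3cΔN-ab KO, so a different RNA fraction in these libraries stays open for the histone change. Among genes above the median mean level 47.4% were higher, and without the first wild type library 5054 genes stayed past the threshold in a DESeq2 refit.

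The direction of change in Mbd3abc KO followed transcript GC content. With called genes in 5 equal classes by GC, 98.4% of the lowest class were higher, against 10.3% of the highest. Across 8046 called genes the rank correlation of log2 fold change with GC was -0.68, where genes are not independent replicates. Set against the share higher at equal GC, glycolysis stayed lower (0 higher, 5.85 expected, adjusted p = 0.0044 over 44 tests by two-sided GC-matched draws). Histones stayed lower too (0 higher, 4.71 expected, adjusted p = 0.0044). The germline list did not stand apart, with 19 higher and 17.9 expected, adjusted p = 0.906, nor did neuroectoderm genes, with 0 higher and 2.37 expected, adjusted p = 0.0792. Epithelial and adhesion genes, 12 higher and 4 lower, stood apart upward, with 4.78 expected to be higher and adjusted p = 0.0044, although the planned Fisher's exact test did not pass (adjusted p = 0.309). Ocln rose 3.96-fold and Krt8 4.78-fold, while the splicing regulator Esrp2 fell 3.59-fold.

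**Figure D1:**
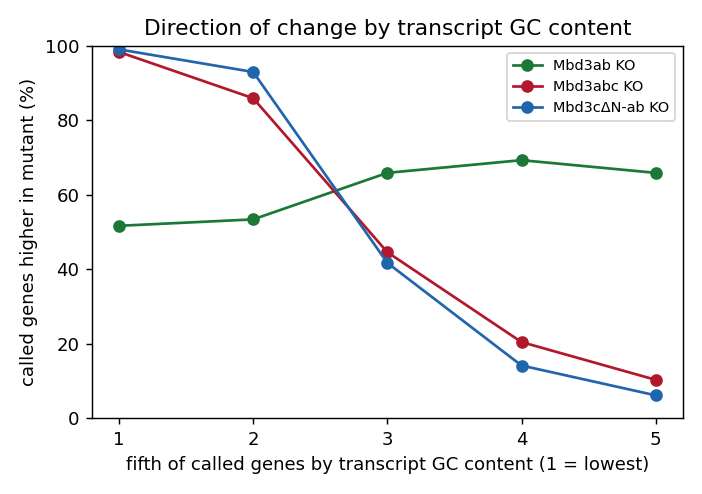
Share of called genes that were higher in the mutant (y axis, percent) in 5 equal classes of the called genes by transcript GC content (x axis, 1 is the lowest), for Mbd3ab KO, Mbd3abc KO and Mbd3cΔN-ab KO. Points are shares of genes, with no error bars. Mbd3abc KO goes from 98.4% to 10.3% and Mbd3cΔN-ab KO from 99.1% to 6.15%, while Mbd3ab KO goes from 51.7% to 65.9%.

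In other groups of Mbd3abc KO, 13 of 17 called p53 targets were higher, with Ccng1 rising 8.37-fold and Trp53inp1 6.55-fold (Fisher adjusted p = 0.243). Of 16 called core pluripotency genes 12 were lower (adjusted p = 0.212): Dppa3 fell 63.0-fold and the threonine dehydrogenase Tdh 3.76-fold. Of 17 called Polycomb genes 10 were higher (adjusted p = 0.937), including Suz12 at 4.22-fold and Bmi1 at 9.95-fold. Of 15 called Wdr5 and COMPASS genes 9 were lower (adjusted p = 0.781), including the histone methyltransferase Kmt2d at 2.30-fold, and Wdr5 itself, named after its value was seen, rose 1.47-fold to 4606 ± 608 normalized reads. The 24 called ribosomal protein genes were of mixed direction, 15 higher and 9 lower, with Rps24 rising 3.13-fold and Rplp0 falling 2.25-fold. Among genes above the median mean level, the largest rises were in a zinc finger cluster on chromosome 4, where Gm13051 rose 151-fold and Gm13154 rose 107-fold. These genes have close paralogs that can share reads, so their separate values are uncertain. The largest falls above that level were in the ribonuclease inhibitor Rnh1, at 67.0-fold, and in Gm20594, at 48.2-fold.

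In the Mbd3cΔN-ab KO line, whose name marks a deletion in c and loss of a and b, 5989 genes were called, 3051 higher and 2938 lower (exact binomial p = 0.148). Germline genes were again mostly higher, 12 of 14, with Dazl rising 13.4-fold, from 14.7 ± 0.106 to 197 ± 11.9 normalized reads (SD, n = 2), and Tex15 rising 22.9-fold. Glycolysis genes were lower in 16 of 17 cases, Slc16a3 by 2.64-fold and Tpi1 by 2.50-fold, and all 12 called histones of the list were lower. The Fisher adjusted p was 0.00241 for glycolysis, 0.00312 for histones and 0.0848 for germline genes. Of 11 called core pluripotency genes 10 were lower (adjusted p = 0.0509), with Dppa3 down to 7.49 ± 3.79 normalized reads (SD, n = 2). Of 13 called epithelial genes 11 were higher (adjusted p = 0.123). Adjusted over the list alone, 17, 12, 14, 11 and 13 members were past the threshold in these 5 lists. For all but the germline list the calls fixed this in advance. As in Mbd3abc KO, Gm13051 of the chromosome 4 cluster rose most among genes above the median mean level, 73.1-fold, and Rnh1 and Gm20594 fell most, 60.4-fold and 78.0-fold. The rank correlation with GC was -0.74 across 5932 called genes. Against the share higher at equal GC, by GC-matched draws, histones stayed lower (adjusted p = 0.0211) and epithelial genes stood apart upward (adjusted p = 0.0044). Neither glycolysis (1 higher, 4.26 expected, adjusted p = 0.183) nor germline genes (12 higher, 10.7 expected, adjusted p = 0.778) stood apart. With at least 2-fold change glycolysis kept 2 called members and lost its call (Fisher's exact test, adjusted p = 0.390). Among genes above the median mean level 43.4% were higher, and 2955 genes stayed past the threshold without the first wild type library in a DESeq2 refit.

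The remaining lists did not pass Fisher's exact test at the main threshold, with Mbd3abc KO given first and Mbd3cΔN-ab KO next. Cholesterol biosynthesis genes were mostly lower, 2 higher and 11 lower (adjusted p = 0.0731), then 2 and 8 (0.263), and neuroectoderm genes were 0 and 7 in Mbd3cΔN-ab KO (0.0554). With at least 2-fold change, cholesterol genes in Mbd3abc KO (1 and 9) and neuroectoderm genes in Mbd3cΔN-ab KO (0 and 6) did pass, each at adjusted p = 0.0192. Naive pluripotency genes were 4 and 11 (0.275), then 4 and 6 (0.870), and formative and primed genes 3 and 8 (0.409), then 3 and 9 (0.313). Trophectoderm genes were 11 and 7 (0.834), then 8 and 6 (1), endoderm genes 7 and 4 (0.870), then 4 and 3 (1), and mesoderm genes 2 and 3 (0.954), then 1 and 2 (0.934). Imprinted genes were 7 and 7 (1), then 5 and 8 (0.772), and DNA methylation genes 7 and 6 (1), then 5 and 4 (1). Interferon response genes were 4 and 6 (0.870), then 2 and 5 (0.628), fibroblast markers 4 and 3 (1), then 1 and 4 (0.525), and genes of the MERVL state 3 and 0 (0.605), then 1 and 0 (1). NuRD subunits were 4 and 4 (1), then 2 and 4 (0.781). In Mbd3cΔN-ab KO, p53 targets were 10 and 3 (0.317), Polycomb genes 9 and 7 (1), Wdr5 and COMPASS genes 5 and 6 (1) and ribosomal proteins 13 and 7 (0.613). Against the share higher at equal GC, by GC-matched draws, ribosomal proteins stood apart upward in Mbd3cΔN-ab KO (7.33 expected, adjusted p = 0.0235) and core pluripotency genes downward (4.22 expected, adjusted p = 0.0427). Adjusted over the list alone, all called members stayed past the threshold except in Mbd3abc KO for mesoderm (2 left), MERVL (0), imprinted (13), interferon (9) and fibroblast (6), and in Mbd3cΔN-ab KO for endoderm (6), mesoderm (1), neuroectoderm (5), MERVL (0), interferon (6) and fibroblast (4). In Mbd3ab KO, endoderm genes were 4 higher and 1 lower (0.943), imprinted 2 and 3 (0.762), formative 1 and 2 (0.870), interferon 0 and 2 (0.439), and no other list beyond those above had more than 2 called members. In Mbd3c KO, epithelial genes were 2 and 0 (1), trophectoderm genes 1 and 1 (0.525), and germline and imprinted genes were called once each.

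Mbd3abc KO and Mbd3cΔN-ab KO shared 5494 called genes, and 5489 of them moved the same way, 2843 higher and 2646 lower. That is 91.7% of the shorter list, where independent lists would share 897 higher and 792 lower. Otx2 rose in both, 4.64-fold and 3.78-fold, and Eomes 6.47-fold and 3.38-fold. The change was larger in Mbd3abc KO for 5037 of the 5494 genes, by a median of 0.34 in absolute log2 fold change in the authors' deposited tables. These values are shrunken, with a slope on the unshrunken log2 ratios of 0.944 in Mbd3abc KO and 0.915 in Mbd3cΔN-ab KO. Part of the difference may come from the shrinkage. An edgeR quasi-likelihood contrast of the 2 mutants on recovered reads was chosen after seeing the data. In it 294 of 5404 genes differed after Benjamini-Hochberg adjustment, and 1663 had an unadjusted p under 0.05. In all 294 the difference lay in the direction of the change in Mbd3abc KO. A gene of opposite sign in the 2 mutants would count so whatever the sizes, and 5 of the 5494 shared genes had opposite signs. Both comparisons used the same wild type libraries. Simulated unchanged mutants with simulated shared controls gave r = 0.50 across genes and a covariance of 0.0394. The observed r was 0.977 and the observed covariance 2.25. The simulated genes were not selected for calls in both mutants as the observed ones were, so these values are not like for like. With 2 wild type libraries the controls could not be split, so part of the excess may come from them, and the GC trend was present in both mutants.

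**Figure D2:**
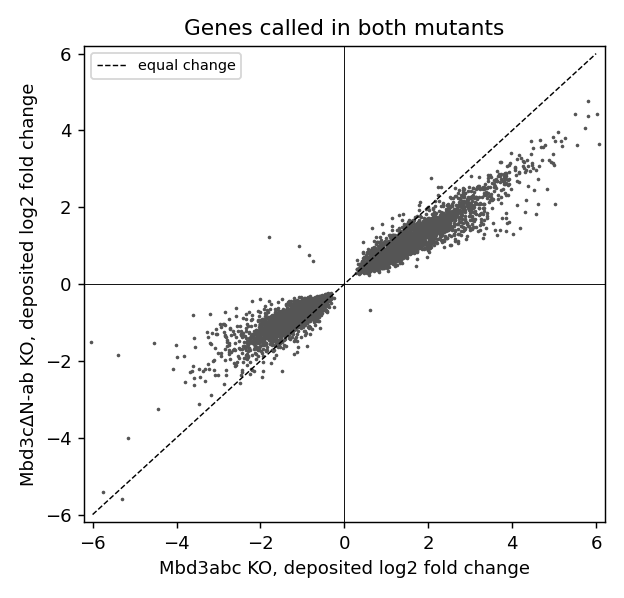
Deposited log2 fold change over wild type of each of the 5494 genes called in both mutants, Mbd3abc KO on the x axis and Mbd3cΔN-ab KO on the y axis. Each point is a gene and the dashed line marks equal change. Nearly all points (5489) lie in the quadrants of equal sign, and 5037 have the larger absolute change in Mbd3abc KO.

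Of the 442 genes called in Mbd3ab KO, 380 were also called in Mbd3abc KO and 377 of these moved the same way, where independent lists would share 87.0 higher and 50.4 lower. Col4a1 rose 18.0-fold in Mbd3abc KO and 17.0-fold in Mbd3cΔN-ab KO, Sohlh2 rose 7.60-fold and 5.95-fold, and Lef1 fell 64.3-fold and 4.72-fold. Bhlhe40 fell 25.2-fold in Mbd3abc KO. With Mbd3cΔN-ab KO, Mbd3ab KO shared 362 called genes, 360 of the same sign. In Mbd3ab KO the rank correlation with GC was 0.13 across 441 genes. Simulated unchanged mutants gave r = 0.498 and 0.501 for these pairs, with covariances of 0.0577 and 0.0578. The observed r was 0.945 (380 genes) and 0.962 (340 genes also listed for Mbd3abc KO, on whose genes the simulation rests). The observed covariances were 3.69 and 2.98. Simulated genes needed no call, unlike the observed ones, so these values are not like for like. Shared controls may still add to the overlap.

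**Figure D3:**
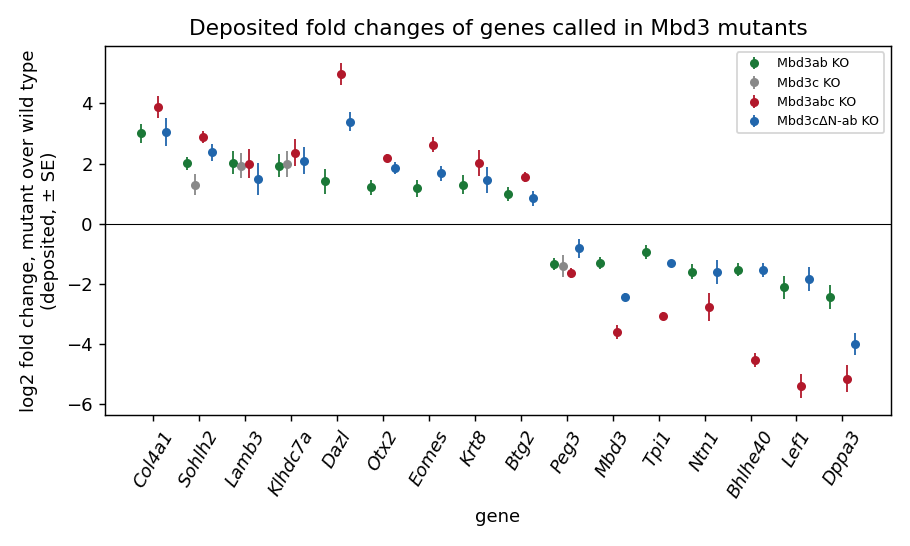
Deposited log2 fold change over wild type (y axis, bars are the deposited SE) of 16 genes (x axis) in each mutant whose table lists them. Points above 0 are higher in the mutant. Lamb3, Klhdc7a and Sohlh2 are above 0 and Peg3 below 0 in all 4 mutants.

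Bmp4 fell in Mbd3c KO but rose in Mbd3abc KO. Mbd3c KO shared 19 of its 38 called genes with Mbd3abc KO, 13 of the same sign (exact binomial p = 0.167), where independent lists would share 13.4 higher and 1.45 lower. With Mbd3ab KO it shared 7 genes, all of the same sign (exact binomial p = 0.0156), against 0.856 higher and 0.0636 lower for independent lists. With Mbd3cΔN-ab KO it shared 10 genes, 9 of the same sign, where independent lists would share 9.64 higher and 1.09 lower. These expected numbers take all calls of the other mutant to lie among the 10759 genes tested in Mbd3c KO. Where some calls lie outside, the expected numbers are too high. The genes shared with Mbd3abc KO and Mbd3cΔN-ab KO therefore cannot be called more or fewer than expected. For these 3 pairs, simulated unchanged mutants gave 62.6%, 64.3% and 59.4% of genes with the same sign. These shares are above the 50% that the binomial test assumes. They cover genes whether or not called in the simulation, so the share to expect among genes called in both stays unknown. Only 5 genes were called in all 4 mutants, each in the same direction: Sohlh2, Lamb3, Klhdc7a and Aldh1l1 rose and Peg3 fell. In Mbd3c KO Sohlh2 rose from 166 ± 20.9 to 498 ± 46.5 normalized reads, Lamb3 7.29-fold, Klhdc7a 10.7-fold and Aldh1l1 3.54-fold. The replicates of Klhdc7a in that mutant differed widely, at 324 ± 261 normalized reads (SD, n = 2). In all, 344 genes were called in at least 3 mutants, 343 of them in a single direction.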

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

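The GC, RNA class and depth tests were chosen after the results were seen, except the GC-matched test of the zinc finger clusters and the test on the lowest of 5 GC classes, whose predictions were written first. No group has the 4 libraries needed to look for a single outlying sample. Genes called with opposite signs in a pair of mutants were singled out. They were taken for their opposite signs, so no p is given for the difference. Between Mbd3abc KO and Mbd3cΔN-ab KO, the protease inhibitor A2m differed by -3.03 in log2 fold change, falling in the first and rising in the second. Dpys differed by -2.07, Clca4 by -1.59, Hydin by -1.35 and AI314180 by 1.29. Between Mbd3ab KO and Mbd3abc KO, Shcbp1 differed by -2, Ppid by -1.39 and Nufip2 by -1.71, and between Mbd3ab KO and Mbd3cΔN-ab KO, Nufip2 differed by -1.40 and Bcam by 0.96. Between Mbd3c KO and Mbd3abc KO, Bmp4 differed by -2.07, Igfbp4 by 2.91, Hist2h2bb by 1.98, Hist3h2a by 2.89, Hist1h2ab by 2.22 and Rpph1 by 2.25. Hist3h2bb-ps differed by 2.94 between Mbd3c KO and Mbd3cΔN-ab KO. These signs were read from the authors' deposited tables.

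The first pattern is that direction followed GC content in Mbd3abc KO and Mbd3cΔN-ab KO. A GC bias of the wild type libraries alone would give Mbd3ab KO the same negative trend, and there the rank correlation was 0.13 across 441 called genes. A bias that the Mbd3ab KO libraries shared with wild type would not show there, so it stays open. A library preparation that differed between groups stays open: replicates of a mutant differed little along GC (largest rank correlation 0.15), which a shared preparation would also give, and preparation cannot be told apart from genotype here. For the genes also called in Mbd3ab KO, GC as the whole cause is argued against by the highest GC class. There all 50 genes that rose in Mbd3ab KO rose in Mbd3abc KO (100%), although 10.3% of that class did. These 50 genes were called in both mutants against the same wild type libraries, which may add to their agreement. In the lowest class only 5 genes fell in Mbd3ab KO and 60% of them rose in Mbd3abc KO, against 98.5% of the other genes there, which is too few to decide.

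The second pattern is the rise of histone and small non-coding RNAs in Mbd3c KO, 61.8% of the genes that rose. A difference in the RNA fraction captured between groups may underlie it, and stays open because both Mbd3c KO libraries share it and the test ran on the genes that show it. Low depth of the shallower library was examined in the deeper one. There all 21 of these RNAs were above both wild type libraries, with a median log2 ratio of 2.07 and a lowest of 1.39. The wild type libraries differed by at most 0.74, so the rise of these RNAs was not confined to the shallower library. However, these RNAs were taken from the calls, and all 38 called genes lay apart from wild type in both mutant libraries. The test therefore cannot exclude an effect of depth on which genes were called. Histone genes went the other way in Mbd3abc KO (48 of 49 called lower) and in Mbd3cΔN-ab KO (41 of 41), and a biological effect of the c isoform was not separable from library preparation.

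The third pattern is the rise of zinc finger gene clusters in Mbd3abc KO and Mbd3cΔN-ab KO, in 3 regions chosen after seeing the data, on chromosomes 4, 17 and 13. Called genes were taken by position alone, so genes of other kinds in these regions are included. In Mbd3abc KO 73 of the 82 were higher, and in Mbd3cΔN-ab KO 65 of the 73. The 82 called genes there had a median log2 fold change of 2.83 in Mbd3abc KO, against a highest value of 2.25 among 10000 GC-matched draws, and the 73 called in Mbd3cΔN-ab KO had 2.08 against 1.74. The regions differed: in Mbd3abc KO the median was 3.74 on chromosome 17 (20 genes) and slightly above that on chromosome 4 (21 genes), but 1.75 on chromosome 13 (41 genes). The regions were picked because they rose, so these draws decide nothing, and the GC trend as the whole cause stays open. Reads shared between paralogs were not tested, since the tables hold no mapping positions, and a biological cause is a hypothesis only.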

How the results depend on the processing

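The alternatives without chromosome 8, with the middle of 5 GC classes, with GC-matched draws and with refits were chosen after seeing the data. No paired analysis was possible because the columns were not assigned to replicate numbers. Tests on all genes (DESeq2 or edgeR, no filter, pseudocount 0.1, an own test) were not run, since the tables hold called genes only. In Mbd3ab KO 232 genes were called at an adjusted p of 0.01, 257 with at least 2-fold change and 222 above the median mean level. Refits called 0 with limma, 0 with edgeR and 434 with DESeq2, tried in that order. In Mbd3c KO the counts were 24, 38 and 19, and refits called 0, 0 and 37. In Mbd3abc KO 4875 genes had at least 2-fold change and 4067 were above the median mean level, and refits called 7725, 7799 and 7694. In Mbd3cΔN-ab KO the same counts were 2428 and 2997, and refits called 5527, 5508 and 5694. Leaving out each library in turn, DESeq2 called from 72 to 303 genes in Mbd3ab KO, from 0 to 38 in Mbd3c KO, from 5054 to 6143 in Mbd3abc KO and from 2955 to 4293 in Mbd3cΔN-ab KO, with no sign changed. The share of genes that were higher turned below 50% above the median mean level, to 46.4% in Mbd3ab KO, 47.4% in Mbd3abc KO and 43.4% in Mbd3cΔN-ab KO. In the middle GC class it was 44.6% in Mbd3abc KO, 41.7% in Mbd3cΔN-ab KO and 85.7% in Mbd3c KO (exact binomial p = 0.125). In Mbd3cΔN-ab KO it was 52.1% at an adjusted p of 0.01, 64.9% with at least 2-fold change and 51.8% without chromosome 8. Mbd3abc KO and Mbd3cΔN-ab KO shared 2248 genes of the same sign with at least 2-fold change and 2798 above the median mean level. At an adjusted p of 0.01, with at least 2-fold change and above the median mean level, Mbd3ab KO shared 193, 226 and 146 with Mbd3abc KO and 167, 202 and 120 with Mbd3cΔN-ab KO. Mbd3c KO shared 5 genes of the same sign with Mbd3abc KO at 0.01, 12 of 14 with at least 2-fold change (exact binomial p = 0.0129) and 3 above the median mean level. It shared 3 at 0.01 and 2 above the median mean level with Mbd3ab KO. The number of lists past the threshold was 6, and 4, 7, 4 and 4 at 0.01, with 2-fold change, above the median mean level and without chromosome 8. In Mbd3abc KO, germline genes lost the call in each, and neuroectoderm genes in all but the 2-fold setting. There core pluripotency and cholesterol genes in Mbd3abc KO and neuroectoderm genes in Mbd3cΔN-ab KO passed (each 0.0192), and glycolysis in Mbd3cΔN-ab KO did not (0.390). By GC-matched draws it was 7 of 44, 3 of them also past the Fisher threshold.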

Other observations

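Some genes called in Mbd3ab KO were not named above. The secreted glycoprotein gene Stc2 fell 4.25-fold and the extracellular matrix gene Frem2 fell 3.32-fold, while the DNA demethylase Tet3 rose 2.36-fold, from 90.7 ± 25.1 to 214 ± 42.7 normalized reads (SD, n = 2). The intermediate filament gene Vim fell 2.31-fold in Mbd3ab KO and 10.2-fold in Mbd3abc KO. The interferon-induced membrane gene Ifitm3 fell 2.37-fold in Mbd3ab KO.

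The prediction for 4 equal stretches of chromosome 8 was written before they were looked at, but after the shift of the whole chromosome was seen. Only genes past a minimum of reads in every library were compared by chromosome. Genes of chromosome 8 were higher in the second Mbd3abc KO library than in the first by a median log2 ratio of 0.51 over 278 genes. The medians of the other chromosomes lay between -0.04 and 0.09. A candidate explanation is a gain of chromosome 8 in part of the cells of that library. Each of 4 stretches of the chromosome's called genes showed it, the lowest with a median of 0.44, as a gain of the whole chromosome would. The ratio of the libraries cannot tell this from a lower dose in the first. Among genes past the read minimum, chromosome 8 was the only chromosome with more genes compared in Mbd3cΔN-ab KO (289) than in Mbd3abc KO. Of these genes 32.2% were higher in Mbd3cΔN-ab KO, against 55.4% in Mbd3abc KO. The genes are called genes only, so a gain stays a hypothesis that a copy number test of the lines would settle. Without chromosome 8, 7794 genes were called in Mbd3abc KO in place of 8132, and 5667 in Mbd3cΔN-ab KO in place of 5989. In number, chromosome 8 thus did not hold more called genes in Mbd3cΔN-ab KO than in Mbd3abc KO. As a share of all called genes, however, it held more in Mbd3cΔN-ab KO, whose table was shorter.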
